A study of Homo sapiens with 7 samples.

How the data were processed

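Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed in T-47D, a luminal breast cancer cell line, for the histone variant H2A.Z and the histone modifications H3K27ac, H3K27me3, H3K36me3, H3K4me2 and H3K9me3. Per the labels, cells were grown to 70 to 80% confluence with 10% serum in 100 mm dishes, nuclei were sonicated, and libraries were sequenced on an Illumina HiSeq 2000. Each mark had 1 library, and an input library was also listed. The input was not analysed here, so 6 of the 7 samples entered the comparisons.

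The deposited file of each mark is a peak list with 4 columns: chromosome, start, end and a peak name. The lists hold no height, enrichment or p-value for a peak, so peaks could be ranked only by width. Per the submitters' processing notes, Bowtie2 2.1.0 and HOMER 4.2 were used and the builds named are hg19 and GRCh37. The notes as used here give no role for either tool, and the peak calling settings, the use of the input and the read depth of each library are not given in the sources used here. The lists are separate for each mark, with 1 list per library. Many peaks share a width of 501 bp, the commonest width over all lists, and a narrower signal cannot be resolved below it. Because depth is unknown, the number of peaks in a list depends on the antibody, the depth and the caller's threshold together, and peak numbers of different marks are not amounts of the mark. A region without a peak may hold signal under the authors' threshold. Copy number of the line was not corrected here.

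Peaks on chromosomes 1 to 22 and X were analysed. Peaks on chromosome Y and on unplaced or alternate contigs were set apart. Coordinates are hg19 and 1-based. Spans of 1 Mb or more without a peak of any list were taken out (58 spans, 172.1 Mb), which left an analysed span of 2772.7 Mb. Overlap meant at least 1 shared bp. For each of the 15 pairs of lists the shared bp and the number of overlapping peaks were compared with 1000 circular shifts of 1 list along its chromosome, which keep the widths and the clustering of both lists. The fold is the observed value over the mean of the shifts. The p-value is two-sided, its smallest possible value is 0.002, and Benjamini-Hochberg adjustment was made over the 15 pairs with a threshold of 0.05. These p-values describe position along the genome in these libraries and carry no replicate error. Intervals (95%) on folds, covered Mb, medians and differences of shares came from 1000 bootstrap draws of 276 windows of about 10 Mb. Shares of peaks have Wilson intervals unless a bootstrap interval is named, and peaks per Mb have exact Poisson intervals. The bootstrap intervals cover only the unevenness along the genome. The Wilson and Poisson intervals cover only counting error with peaks taken as independent, so they are too narrow where peaks cluster. Correlations over the 23 chromosomes used peaks per Mb, with 100000 permutations.

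H3K36me3 domains were H3K36me3 peaks merged within 1 kb and at least 5 kb long. Coverage by the other lists was measured inward and outward from their edges, up to the next H3K36me3 region. Merged regions of several lists were unions of overlapping peaks. The shift method was tested on simulated data, with 8000 peaks per list on 4 chromosomes and 200 shifts. With 0, 10 and 30% of peaks planted on the other list it returned folds of 0.939, 5.42 and 14.6. With overlaps excluded it returned 0, which was fixed by removing every overlapping peak. The simulated peaks were placed at random without clustering, so this check does not cover clustered lists.

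The tests, the settings to be varied and the rule for named regions were fixed before the data were examined. The rule takes the 3 widest peaks of each list and the 3 longest overlaps of each pair discussed. The alternatives were the peaks wider than the median of their list, an overlap of at least 50% of the shorter peak, autosomes only, peaks merged within 1 kb, the widest 1% of peaks left out, shifts over the whole span, independent placement of peaks, removal of chromosome 19 for H3K36me3 with H3K27me3 and with the list labelled H3K9me3, and width-matched H3K4me2 peaks. Shifts within windows of about 5 Mb, and the list labelled H3K9me3 set beside the list labelled H2A.Z in each comparison, H3K27me3 and H3K36me3 on H3K4me2 peaks with and without H3K27ac, and chromosome 19 for the list labelled H2A.Z, were added after seeing the data. The edges of H3K36me3 domains, the classes by width and the shares on chromosome 19, both with 200 shifts for the share expected and intervals on the observed share alone, and the arms of chromosomes, taken on either side of the peak-free span at the centromere, were also examined after the planned comparisons. Marks at gene starts, marks over gene bodies and the planned gene lists were not analysed, since a gene annotation of hg19 was not used here, and regions are therefore given by coordinates without gene names. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.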

Results

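The series was designed to relate histone modification to gene regulation in T-47D cells, an estrogen receptor-positive breast cancer line. The data were 6 peak lists, with 1 library per mark and no replicates. As background, H3K4me2 and H3K27ac mark promoters and enhancers, H2A.Z is a histone variant found at promoters and enhancers, H3K36me3 marks transcribed gene bodies, H3K27me3 marks Polycomb-repressed regions and H3K9me3 marks heterochromatin. The lists labelled H2A.Z and H3K9me3 related to H3K4me2 and H3K27ac in directions opposite to this background, as the values below show. For the list labelled H3K9me3 this concerned a part, since 10691 of its 20177 merged regions held neither H3K4me2 nor H3K27ac. Both lists are therefore named throughout as the list labelled H2A.Z and the list labelled H3K9me3. Every direction given for either holds for the list under that label.

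H3K36me3 covered more of the genome than any other mark and formed the longest domains, whereas the lists labelled H2A.Z and H3K9me3 consisted mostly of short peaks. The 52558 H3K36me3 peaks covered 100.6 Mb (95% bootstrap interval 91.2 to 109.9), or 3.63% of the analysed span. H3K4me2 had 64561 peaks over 52.7 Mb (49.0 to 56.4) and H3K27me3 had 64492 peaks over 48.5 Mb (43.1 to 53.8). H3K27ac had 31453 peaks over 35.8 Mb (32.5 to 39.2). The list labelled H2A.Z had 52188 peaks over 33.9 Mb (29.0 to 38.7) and the list labelled H3K9me3 had 20451 peaks over 13.4 Mb (12.2 to 14.6).

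Median peak width was 723 bp for H3K36me3, 653 bp for H3K27ac and 628 bp for H3K4me2. It was 501 bp for H3K27me3 and for both lists labelled H2A.Z and H3K9me3. Peaks over 5 kb made up 8.65% of the H3K36me3 list (4545 peaks) and 1.79% of the H3K27ac list (564 peaks). There were 97 such peaks for H3K27me3, 10 in the list labelled H2A.Z and 0 in the list labelled H3K9me3. The widest H3K36me3 peaks spanned 75.7 kb on chromosome 17 (5245825 to 5321485), 74.8 kb on chromosome 11 (47794066 to 47868831) and 74.0 kb on chromosome 11 (93398403 to 93472391). The widest H3K27ac peaks spanned 39.6 kb on chromosome 22 (29185842 to 29225458), 34.0 kb on chromosome 4 (37451046 to 37485061) and 30.5 kb on chromosome 2 (11669584 to 11700094). Each of these 3 H3K27ac peaks overlapped H3K4me2 and H3K36me3 peaks. The widest H3K4me2 peaks lay on chromosome 16 (85485812 to 85509671, 23.9 kb), chromosome 10 (95193379 to 95206327) and chromosome 17 (73082948 to 73095158). All 3 overlapped H3K36me3, and those on chromosomes 16 and 17 overlapped H3K27ac. The widest H3K27me3 peaks lay on chromosome 11 (45646459 to 45657451), chromosome 10 (6979884 to 6989717) and chromosome 9 (140885128 to 140894606), and all 3 overlapped a peak of the list labelled H2A.Z. Of the widest peaks in that list, those on chromosome 7 (56532446 to 56539164) and chromosome 11 (131870905 to 131877577) overlapped no other list, and that on chromosome 4 (393377 to 399703) overlapped H3K27me3.

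The pairwise comparison asked which marks share regions. The lists fell on 2 sides. H3K4me2, H3K27ac and the list labelled H3K9me3 shared regions, and H3K27me3 shared regions with the list labelled H2A.Z. The lists labelled H2A.Z and H3K9me3 overlapped each other 2.32-fold over the shifts (bootstrap interval 1.95 to 2.76), 1.40-fold among peaks wider than the median of their list and 1.69-fold with shifts within 5 Mb windows. Labelled H3K9me3 peaks of at most 501 bp overlapped the list labelled H2A.Z 3.07-fold over the shifts (2.50 to 3.71). Those of 501 bp to 1 kb did so 1.43-fold (1.01 to 1.92), but those of 1 to 2 kb only 0.288-fold (0.171 to 0.436). By width of the labelled H2A.Z peaks the excess stayed, from 1.86-fold at most 501 bp to 3.12-fold from 2 to 5 kb. H3K27ac and H3K27me3 almost never met, and neither did H3K36me3 and H3K27me3. All 15 pairs passed the adjusted threshold, 14 of them with an adjusted p of 0.00214, and the list labelled H3K9me3 with H3K27me3 passed at 0.038 with a fold of 0.874 (0.723 to 1.03). That last call was lost with the widest 1% of peaks left out (adjusted p 0.254) and with shifts over the whole span (adjusted p 0.162). It was kept among wider peaks (0.250-fold, adjusted p 0.00214) and with shifts within 5 Mb windows (0.744-fold, adjusted p 0.00214), and the count of overlapping peaks still passed without the widest 1% (adjusted p 0.046). That count lost its call with an overlap of at least 50% of the shorter peak (0.999-fold, adjusted p 0.983) and with shifts over the whole span (0.897-fold, adjusted p 0.0879). The direction turned with the width of the labelled H3K9me3 peaks. Those of at most 501 bp overlapped H3K27me3 1.27-fold over the shifts (1.08 to 1.48). Those of 501 bp to 1 kb did so 0.455-fold (0.339 to 0.567), and those of 1 to 2 kb 0.111-fold (0.0583 to 0.176). With 1 library per mark, these tests concern the positions of the peaks in these libraries.

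**Figure D1:**
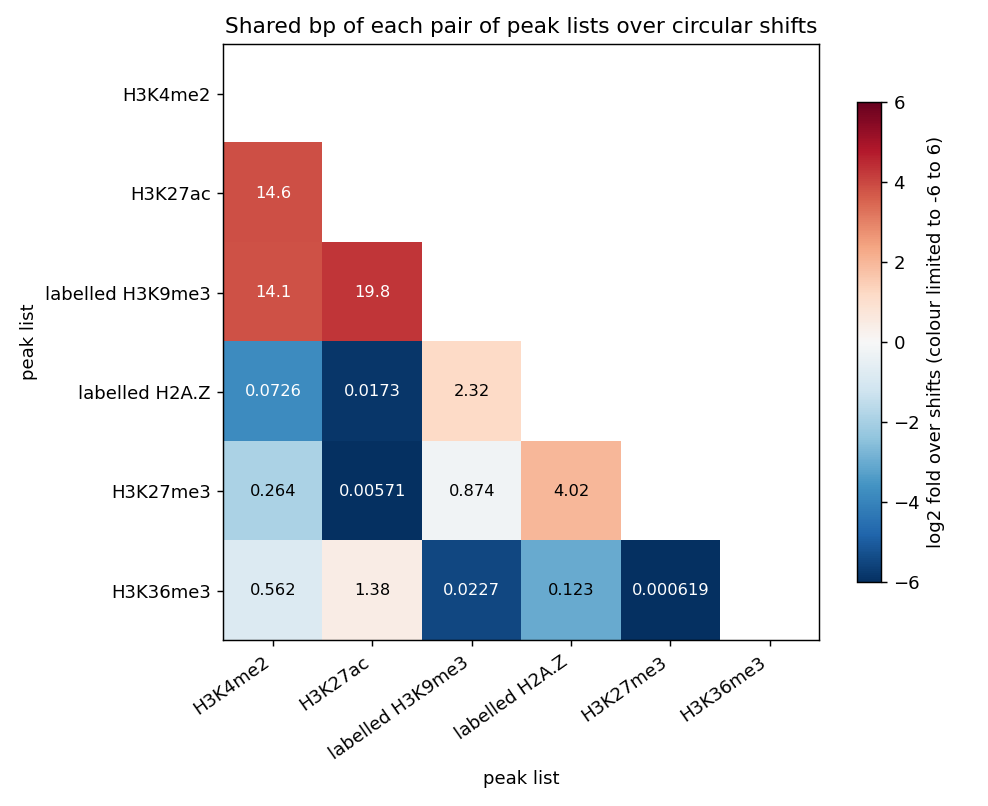
Shared bp of each pair of lists divided by the mean of 1000 circular shifts, printed in each cell and coloured on a log2 scale. The list labelled H3K9me3 had folds of 14.1 and 19.8 with H3K4me2 and H3K27ac, and the list labelled H2A.Z had folds of 0.0726 and 0.0173.

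H3K4me2 and H3K27ac marked many regions together. Of the H3K27ac peaks, 48.8% (Wilson interval 48.3 to 49.4) overlapped H3K4me2, and 25.7% (25.3 to 26.0) of H3K4me2 peaks overlapped H3K27ac. Shared bp were 14.6-fold over the shifts (bootstrap interval 13.7 to 15.5). The longest shared stretches lay on chromosome 2 (20664603 to 20675475, 10873 bp), chromosome 8 (96076486 to 96083911, 7426 bp) and chromosome 3 (174575415 to 174582566, 7152 bp). The share rose with width, from 30.0% of H3K27ac peaks of at most 501 bp (bootstrap interval 28.5 to 31.5) to 88.5% of those over 5 kb (85.6 to 91.0). Wider peaks also meet another list more often by length, and shifts gave 3.61% and 17.1% for these classes. Over the shifts the excess was 8.33-fold (7.91 to 8.73) in the narrowest class, 12.1-fold (11.7 to 12.6) from 501 bp to 1 kb and 5.18-fold (5.01 to 5.33) over 5 kb, so it did not rise steadily with width.

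These active regions held almost no peak of the list labelled H2A.Z. Only 24 of its 52188 peaks overlapped H3K27ac, where the shifts gave 1168, and shared bp were 0.0173-fold (0.00936 to 0.0269), and 0.00479-fold among peaks wider than the median of their list. With H3K4me2, 159 peaks overlapped against 2017 in the shifts, and shared bp were 0.0726-fold (0.0555 to 0.0908), and 0.0217-fold among wider peaks. Among 130747 merged regions of H3K4me2, H3K27ac and the list labelled H2A.Z, 14892 held both H3K4me2 and H3K27ac without the list labelled H2A.Z, and 9 held all 3. The direction is opposite to the background for H2A.Z and holds for the list under that label.

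The list labelled H3K9me3 met the active regions more often than the shifts gave. Of its peaks, 30.4% (bootstrap interval 28.1 to 32.8) overlapped H3K27ac and 35.3% (33.0 to 37.6) overlapped H3K4me2. Shared bp were 19.8-fold (18.2 to 21.6) and 14.1-fold (13.2 to 14.9) over the shifts, and 32.5-fold and 23.3-fold among wider peaks. Of the 20177 merged regions that held this list, 9486 held H3K4me2 or H3K27ac, 4509 of them both, and 10691 held neither. The longest overlaps with H3K27ac were on chromosome 12 (53762615 to 53765926, 3312 bp), chromosome 6 (157040313 to 157043260, 2948 bp) and chromosome 3 (38178154 to 38180771, 2618 bp). Among peaks of 1 to 2 kb in the list labelled H3K9me3, 65.0% overlapped H3K27ac (bootstrap interval 63.0 to 67.2), against 19% (17 to 21.2) of those of at most 501 bp. Shifts gave 3.14 and 2.09% for these classes, an excess of 20.7-fold (20 to 21.4) and 9.09-fold (8.11 to 10.1). Its 3 widest peaks, on chromosome 3 (159480470 to 159484347), chromosome 10 (77159936 to 77163785) and chromosome 5 (180614861 to 180618633), all overlapped H3K27ac. This direction too is opposite to the background for the label.

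**Figure D2:**
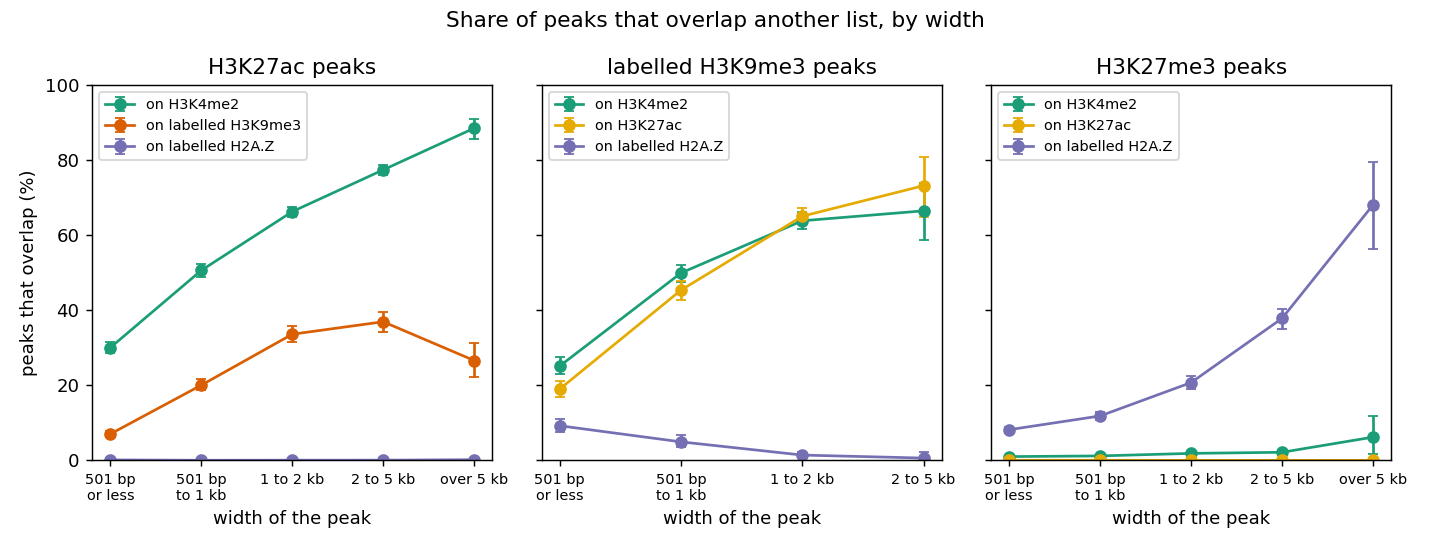
Percent of peaks that overlap another list, by peak width, for H3K27ac, the list labelled H3K9me3 and H3K27me3, with 95% bootstrap intervals over windows. Of peaks over 5 kb, 88.5% of H3K27ac were on H3K4me2, where shifts gave 17.1%, and 68.0% of H3K27me3 were on the list labelled H2A.Z, where shifts gave 13.8%.

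The next comparison asked whether H2A.Z on H3K4me2 regions differs with H3K27ac. Peaks of the list labelled H2A.Z touched 5 of 16565 H3K4me2 peaks with H3K27ac (0.0302%) and 154 of 47996 without (0.321%). The difference was -0.291 percentage points (bootstrap interval -0.368 to -0.220). It was -0.187 when H3K4me2 peaks were matched by width, and -0.0397 (-0.080 to -0.00199) among wider peaks, where it rested on 1 peak with H3K27ac against 12 without. The list labelled H3K9me3 went the other way. It touched 22.5% of H3K4me2 peaks with H3K27ac and 7.30% of those without, a difference of 15.2 points (14.1 to 16.4). Matching by width raised the share without H3K27ac to 11.5%, which left 11 points (10.1 to 11.9). H3K36me3 touched 6.61% and 3.22%, a difference of 3.39 points (2.99 to 3.83), which was 2.71 when matched by width and 1.68 with an overlap of at least 50% of the shorter peak. Both directions for the lists labelled H2A.Z and H3K9me3 depend on their labels, and the overlaps with active marks run opposite to the background for those labels.

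H3K27me3 was kept apart from H3K27ac, and less strictly from H3K4me2. Of 31453 H3K27ac peaks, 11 overlapped H3K27me3 (0.035%, Wilson interval 0.0195 to 0.0626), where the shifts gave 1541 overlapping H3K27me3 peaks. Of H3K4me2 peaks, 767 overlapped H3K27me3 (1.19%, 1.11 to 1.27), and shared bp were 0.264-fold (0.230 to 0.303), and 0.159-fold among wider peaks. The difference between the 2 shares was 1.15 percentage points (bootstrap interval 1.0 to 1.33), and 0.482 (0.397 to 0.584) among peaks wider than the median of their list. H3K27me3 touched 14 of 16565 H3K4me2 peaks with H3K27ac (0.0845%) and 753 of 47996 without (1.57%). Matching by width put the share without H3K27ac at 1.43%. The longest H3K4me2 and H3K27me3 overlaps were 1112 bp on chromosome 7 (1626234 to 1627345), 1082 bp on chromosome 12 (132689017 to 132690098) and 1063 bp on chromosome 7 (1276729 to 1277791).

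H3K27me3 met the list labelled H2A.Z instead. Of its peaks, 11.8% (11.5 to 12.0) overlapped that list, with shared bp 4.02-fold over the shifts (bootstrap interval 3.5 to 4.49) and 2.94-fold when shifts stayed within 5 Mb windows. Of H3K27me3 peaks of at most 501 bp, 8.17% overlapped the list labelled H2A.Z (7.35 to 8.93), where shifts gave 2.84%. Of the 97 peaks over 5 kb, 68.0% did (56.2 to 79.4), where shifts gave 13.8%. The excess over the shifts was 2.88-fold (2.59 to 3.14) and 4.93-fold (4.07 to 5.75) in these classes, so the share rose further than length alone gave. The longest such overlaps were 3748 bp on chromosome 11 (75393418 to 75397165), 3437 bp on chromosome 8 (49077325 to 49080761) and 3423 bp on chromosome 11 (45649420 to 45652842). As above, the label of this list is in doubt.

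The next question was how H3K36me3, a mark of transcribed gene bodies, relates to the repressive marks. H3K36me3 and H3K27me3 excluded each other almost completely. Of 64492 H3K27me3 peaks, 4 overlapped H3K36me3, where the shifts gave 2736 H3K36me3 peaks on H3K27me3, and shared bp were 0.000619-fold. The list labelled H3K9me3 also avoided H3K36me3, with 32 of 20451 peaks overlapping (0.156%, Wilson interval 0.111 to 0.221) and 0.0227-fold shared bp (0.0153 to 0.0312), or 0.000504-fold among wider peaks. Of the list labelled H2A.Z, 271 of 52188 peaks were on H3K36me3 (0.519%), with 0.123-fold shared bp (0.0763 to 0.185).

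Chromosome 19, which holds large clusters of zinc finger genes, was set apart in the plan for H3K27me3 and the list labelled H3K9me3, and the list labelled H2A.Z was added after seeing the data. On chromosome 19, 88 of 440 peaks in the list labelled H2A.Z overlapped H3K36me3 (20%, Wilson interval 16.5 to 24.0), against 183 of 51748 on the other chromosomes (0.354%, 0.306 to 0.409). The share was 56.6 times higher on chromosome 19, where H3K36me3 is dense, and shifts alone gave a ratio of 2.68. Against the shifts, the number of overlapping peaks in this list was 1.45-fold on chromosome 19 and 0.0687-fold elsewhere. For the list labelled H3K9me3, 0 of 424 peaks on chromosome 19 overlapped H3K36me3 (Wilson upper bound 0.898%), against 32 of 20027 elsewhere. For H3K27me3 it was 0 of 992, against 4 of 63500. Shared bp of the list labelled H2A.Z and H3K36me3 were 1.88-fold over shifts within 5 Mb windows of chromosome 19 (overlapping H3K36me3 peaks 1.38-fold, 71 against 51.6, adjusted p 0.030), and 0.0812-fold over shifts without chromosome 19. The longest overlaps of these lists were 3718 bp on chromosome 19 (12186210 to 12189927), 3476 bp on chromosome 7 (5099890 to 5103365) and 2205 bp on chromosome 19 (58774007 to 58776211).

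H3K27ac and H3K36me3 overlapped in part. Of H3K27ac peaks, 12.9% (12.5 to 13.3) touched H3K36me3, and shared bp were 1.38-fold (1.22 to 1.57). The shared bp were 1.0-fold, with an adjusted p of 0.897, when shifts stayed within 5 Mb windows, and 0.821-fold among peaks wider than the median of their list. The count of overlapping peaks stayed above the shifts, 1.81-fold in the main setting, 1.37-fold within 5 Mb windows and 1.24-fold among wider peaks. The longest overlaps were 6046 bp on chromosome 22 (29189738 to 29195783), 4637 bp on chromosome 14 (74060674 to 74065310) and 4556 bp on chromosome 15 (41140863 to 41145418). H3K4me2 and H3K36me3 shared fewer bp than the shifts gave, 0.562-fold (0.513 to 0.612).

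Around the edges of the 5371 H3K36me3 domains of 5 kb or more, active marks were densest just outside among the zones compared. From 1 to 4 kb outside, H3K27ac covered 13.1% of the sequence (bootstrap interval 12.1 to 14.2), 10.1 times its share of the analysed span. H3K4me2 covered 9.50% (8.93 to 10.1), 5.0 times its share, and the list labelled H3K9me3 covered 3.17% (2.88 to 3.5), 6.55 times its share. From 20 to 30 kb outside these were still at 2.25 (1.95 to 2.56), 2.08 (1.86 to 2.3) and 2.08 (1.75 to 2.43) times their share. The edges still followed fell from 10742 at 0.5 kb to 1943 at 29.5 kb outside, so the zones do not rest on the same edges. In the finer profile over distance, H3K27ac ran from 3.08 times its share at 20.5 kb to 2.18 at 28.5 kb outside. The list labelled H2A.Z was at 0.0693 times its share from 1 to 4 kb outside (0.029 to 0.124), 0.449 from 20 to 30 kb outside (0.344 to 0.567) and 0.105 from 1 to 5 kb inside (0.0257 to 0.226). From 1 to 5 kb inside, H3K27ac was at 1.43 times its share (1.18 to 1.70), H3K4me2 at 0.284 (0.232 to 0.341), and the list labelled H3K9me3 at 0.00324 (0 to 0.0102). H3K27me3 covered nothing in that inner zone, 0.0401% from 1 to 4 kb outside (0.0186 to 0.0662), and 1.78% from 20 to 30 kb outside (1.46 to 2.12), which was 1.02 times its share of the span.

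**Figure D3:**
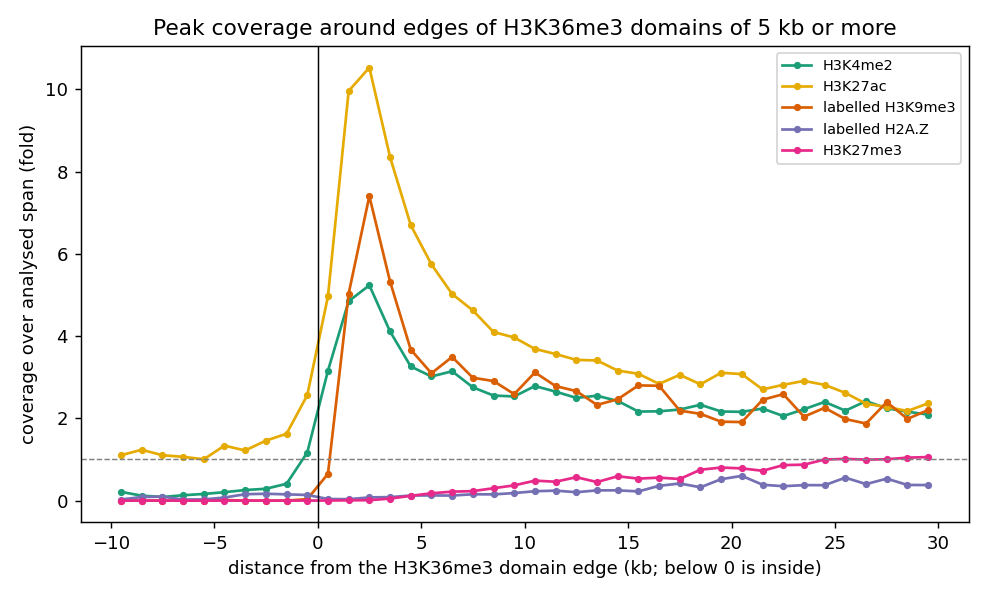
Coverage by 5 lists, as fold over their share of the analysed span, against distance in kb from the edges of H3K36me3 domains of 5 kb or more (below 0 is inside). H3K27ac reached 10.5-fold at 2.5 kb outside, and H3K27me3 stayed below 1 until more than 20 kb outside. The edges still followed fell from 10742 at 0.5 kb to 1943 at 29.5 kb outside.

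The distribution over chromosomes asked where each mark was dense. H3K27ac and H3K36me3 were densest on chromosome 19, with 33.9 (exact Poisson interval 32.4 to 35.5) and 48.8 (47 to 50.7) peaks per Mb. Peaks of the list labelled H2A.Z were densest on chromosomes 20 and 11, with 46.7 and 46.3 peaks per Mb, and numbered 1.71 per Mb (1.46 to 2.0) on chromosome 13 and 1.76 on chromosome 2. H3K27me3 was densest on chromosome 20 (49.2 per Mb) and sparsest on chromosome X (4.22), and the list labelled H3K9me3 ranged from 15.7 on chromosome 11 to 1.84 on chromosome X. In covered kb per Mb, the highest chromosome exceeded the lowest 32.9-fold for the list labelled H2A.Z (bootstrap interval 19.8 to 51.7), 15.2-fold for H3K27me3 (7.79 to 42.8) and 8.41-fold for the list labelled H3K9me3 (4.81 to 15.8). The ratio was 7.29 for H3K27ac, 6.44 for H3K36me3 and 5.02 for H3K4me2.

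**Figure D4:**
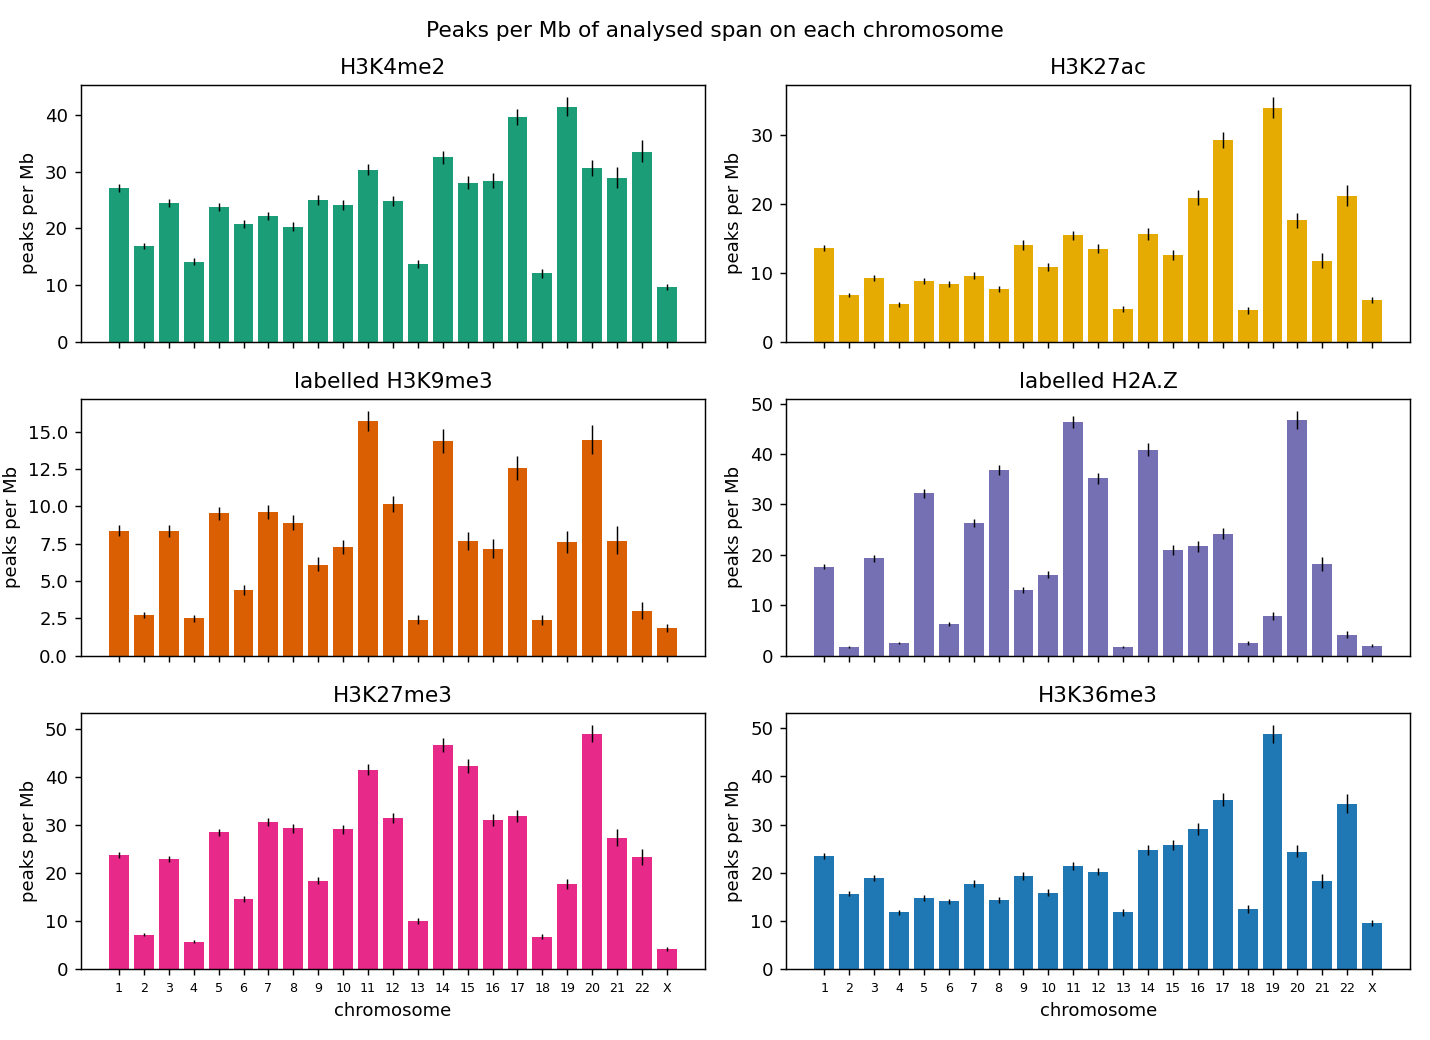
Peaks per Mb of analysed span on each chromosome for the 6 lists, with exact Poisson intervals. The list labelled H2A.Z had 46.7 peaks per Mb on chromosome 20 and 1.71 on chromosome 13, and H3K27ac was densest on chromosome 19 at 33.9.

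The lists labelled H2A.Z and H3K9me3 were dense on the same chromosomes. Over the 23 chromosomes, Pearson's r was 0.934 (permutation p 1e-05, the smallest possible, adjusted 2.5e-05) and Spearman's rho was 0.936 (permutation p 1e-05, adjusted 2.5e-05), and r was 0.902 without the 2 chromosomes farthest from the median. For H3K27me3 and the list labelled H2A.Z the values were r of 0.885 and rho of 0.900 (both permutation p 1e-05, adjusted 2.5e-05), and r of 0.849 without those 2. H3K27ac and H3K36me3 gave r of 0.962 and rho of 0.950 (both permutation p 1e-05, adjusted 2.5e-05), and r of 0.933 without the 2 farthest. H3K27ac and the list labelled H2A.Z gave r of 0.214 (permutation p 0.330, adjusted 0.353) and rho of 0.485 (permutation p 0.0201, adjusted 0.0215), and r of 0.460 without the 2 farthest. These were among 15 pairs examined, and chromosomes are not replicates.

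The lists differed in how density changed between the arms of chromosome 1. Before the peak-free span of 121329134 to 142539737 the list labelled H2A.Z had 2.45 peaks per Mb (2.17 to 2.74), and after it 34.8 (33.6 to 35.9). H3K27me3 had 10.3 and 39.3 peaks per Mb, and the list labelled H3K9me3 had 3.53 and 13.8. H3K27ac differed less, with 13.0 (12.4 to 13.7) and 14.3 (13.6 to 15), H3K4me2 rose from 25.3 to 29.3 and H3K36me3 fell from 25.9 to 20.8. On chromosome 8 the list labelled H2A.Z had 12.1 peaks per Mb before the span of 43790240 to 46847005 and 47.6 after it, and H3K27ac had 6.86 and 8.04. On other chromosomes H3K27ac changed too, from 15.4 to 4.75 on chromosome 6 (13.7 to 2.43 for the list labelled H2A.Z), from 7.57 to 17.4 on chromosome 9 (1.69 to 18.9) and from 8.29 to 24.8 on chromosome 20 (29.2 to 60.5). Over 19 chromosomes with 2 arms, H3K27ac changed in the direction of the list labelled H2A.Z on 15 (exact p 0.0192, adjusted 0.024), where chance gives 9.5. H3K4me2 did so on 15 (the same p), H3K27me3 on 17 (p 0.000729, adjusted 0.00364), the list labelled H3K9me3 on 16 (p 0.00443, adjusted 0.0111) and H3K36me3 on 11 (p 0.648, adjusted 0.648).

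**Figure D5:**
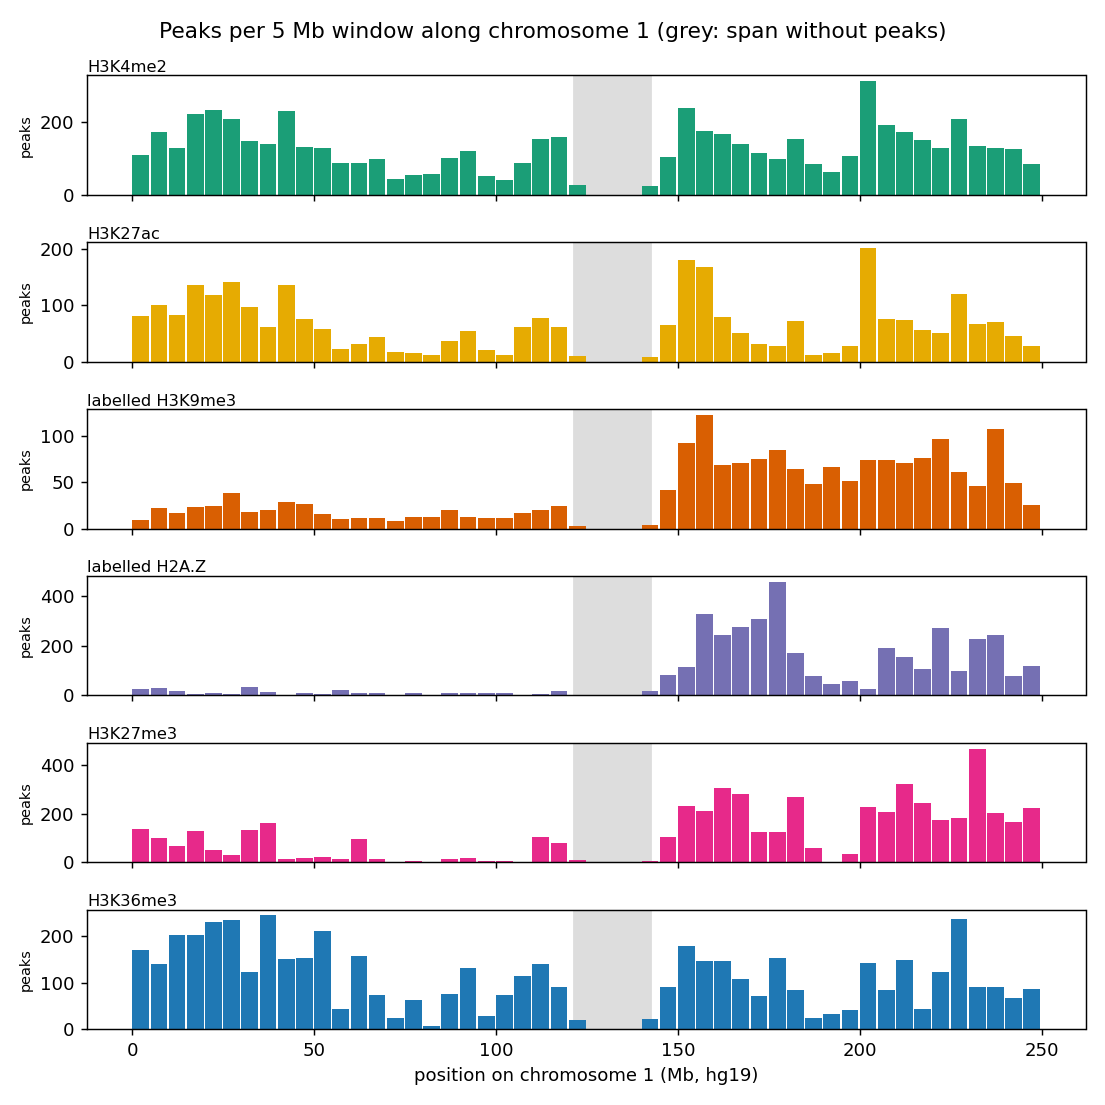
Peaks of each list in 5 Mb windows along chromosome 1 (position in Mb, hg19), with the span without peaks in grey. The list labelled H2A.Z had 294 peaks before that span and 3707 after it, while H3K27ac had 1562 and 1522.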

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

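The peaks described here lie outside the comparisons and were counted after the lists were read, and no explanation was tested for them. Each list held more than 3 peaks on chromosome Y and on unplaced or alternate contigs together, the count above which they were flagged. That limit is a rule for flagging and not a number expected on contigs. The list labelled H2A.Z had 324 such peaks and the list labelled H3K9me3 had 274, followed by H3K27me3 with 219, H3K4me2 with 174, H3K27ac with 157 and H3K36me3 with 147. The alternate haplotype contigs among them held 3 H3K4me2 peaks, 2 H3K27ac peaks and 1 peak each of H3K36me3 and the list labelled H3K9me3. Chromosome Y held 28 peaks of the list labelled H2A.Z and 22 of the list labelled H3K9me3. It held 8 H3K27me3 peaks, 5 H3K36me3 peaks, 3 H3K4me2 peaks and 3 H3K27ac peaks.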

How the results depend on the processing

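The shifts within 5 Mb windows, chromosome 19 for the list labelled H2A.Z and the settings for H3K4me2 peaks or regions with the list labelled H3K9me3, H3K27me3 or H3K36me3 were chosen after seeing the data. Of 231 pair folds recomputed under alternatives, 225 kept their direction and their side of the threshold, as did all 29 differences of shares, though not their size: 22 of the folds moved by more than 1.5 times, 20 of them among peaks wider than the median (H3K27ac with H3K27me3 from 0.00571 to 0.000629 in bp). Shared bp of H3K27ac with H3K36me3 were reversed at 0.821-fold among peaks wider than the median of their list and fell to 1.0-fold with shifts within 5 Mb windows, while overlapping peaks kept 1.24 and 1.37-fold. The list labelled H3K9me3 with H3K27me3 lost its call with the widest 1% left out for bp (0.932-fold, adjusted p 0.254) and with shifts over the whole span (0.911-fold for bp, adjusted p 0.162, and 0.897-fold for peaks, adjusted p 0.0879), and with an overlap of at least 50% of the shorter peak (0.999-fold, adjusted p 0.983). The cause was not tested for either pair. The 50% minimum was applied to peaks alone, since shared bp and merged regions do not use one. Keeping peaks wider than the median left, by its construction, 31950 H3K4me2, 15722 H3K27ac, 17334 labelled H2A.Z, 7168 labelled H3K9me3, 27178 H3K27me3 and 26268 H3K36me3 peaks, covering 36.2, 27.6, 16.4, 6.77, 29.8 and 86.6 Mb. It left 7859 regions with H3K4me2 and H3K27ac, 1857 with the list labelled H3K9me3 in addition, and 1 with the list labelled H2A.Z in addition. Merging within 1 kb, which adds the gaps, raised coverage to 56.3 (H3K4me2), 37.8 (H3K27ac), 37.7 (labelled H2A.Z), 55.0 (H3K27me3) and 107.6 Mb (H3K36me3). The other gene start windows, gene body limits, start site choices and backgrounds planned for genes were not run, since no annotation of the build was used here. Read depth is unknown, so a missing overlap can be a peak under the threshold, and 1 library per mark gives no replicate check. No paired analysis was possible because each mark has 1 library.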

Other observations

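Of the tests below, those on the flanks of peak-free spans and on density steps within chromosomes were written before their results were seen, and the others were chosen only after the result was seen.

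Long peak-free spans were not limited to the centromeres. No list had a peak on chromosome 6 from 28477911 to 29843094 and from 29849450 to 32527821, spans of 1.37 and 2.68 Mb in the region of the major histocompatibility complex. Alternate contigs of chromosome 6 held 1 H3K4me2 and 1 H3K27ac peak, so such contigs were among the mapping targets. Whether reads could be placed in these spans was not examined, so the absence of peaks does not show absence of the marks. On chromosome 16 the span from 61952731 to 66312096 (4.36 Mb) and that from 50817921 to 53086439 (2.27 Mb) had no peak either. On chromosome X there was a span of 3.87 Mb from 110928700 to 114795668. In merged regions of all 6 lists, 610 held H3K4me2 and H3K27me3 with no other mark, 7115 held the list labelled H2A.Z with H3K27me3 only, and 4275 held H3K4me2, H3K27ac and the list labelled H3K9me3 only.

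Active marks were avoided by the list labelled H2A.Z and met by part of the list labelled H3K9me3. Of the 20177 merged regions with the list labelled H3K9me3, 10691 held neither H3K4me2 nor H3K27ac. Its peaks of at most 501 bp overlapped the list labelled H2A.Z 3.07-fold over the shifts (2.50 to 3.71). With shifts within 5 Mb windows, the list labelled H3K9me3 and H3K27ac shared 17.3-fold bp (bootstrap interval 16.0 to 18.9). For this overlap, copy number alone is therefore argued against. The overlap had been seen before the test was chosen, and the test does not cover the list labelled H2A.Z. The list labelled H2A.Z shared 0.0194-fold (0.0111 to 0.0291) with H3K27ac under the same shifts. For this list, background peaks placed without regard to the marks are thus argued against. Because the value restates the avoidance itself, background peaks that also avoid active regions stay open, and the use of the input is unknown. The 1.88-fold (1.25 to 2.53) of this list with H3K36me3 came from chromosome 19 alone, where overlaps had been seen, and does not bear on this. A candidate explanation is that the labels of these lists were exchanged. The share of the list labelled H2A.Z on H3K36me3 was 56.6 times higher on chromosome 19 than elsewhere (shifts gave 2.68 times). The list labelled H3K9me3 showed no such rise. Against the shifts, overlapping peaks of the list labelled H2A.Z were 1.45-fold on chromosome 19 and 0.0687-fold elsewhere. Most of the ratio therefore came from avoidance elsewhere. Zinc finger gene clusters on that chromosome carry H3K9me3 and H3K36me3 together as background, but the overlaps were not placed in genes. The overlap on chromosome 19 had been seen before this test was chosen, so it gives no separate support. A second test left an exchange open, since near peak-free spans (within 2 Mb) the ratio of the list labelled H2A.Z to the list labelled H3K9me3 was 1.2 times that elsewhere (0.904 to 1.46). An exchange at the antibody, the library or the file cannot be separated with these data, and no biological explanation was tested.

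The lists labelled H2A.Z and H3K9me3 and H3K27me3 were concentrated on the same chromosomes. Copy number of T-47D acting on lists called at a fixed threshold and any other shared regional density are candidate explanations that 2 tests did not separate. At the strongest step of the list labelled H2A.Z, H3K27me3 moved the same way in 23 of 23 chromosomes (median log2 change 1.05), the list labelled H3K9me3 in 21 (1.18), H3K27ac in 19 (0.436), H3K4me2 in 17 (0.341) and H3K36me3 in 14 (0.0896), and labelled H3K9me3 peaks away from active marks followed the list labelled H2A.Z with rho 0.938 (r 0.959, both permutation p 1e-05, r 0.950 without the 2 farthest chromosomes), as did those on active marks with rho 0.732 (permutation p 0.00015) and r 0.680 (p 0.00026, 0.654 without those 2). The number of active regions could not be decided on as a cause, since rho with H3K27ac was 0.485, between the bounds set for it, and a further test over arms, added because of that, gave a median absolute log2 ratio of 1.13 (0.768 to 1.74), an interval that reached below the 1 set as its bound. Copy number itself was not measured here, and no biological explanation was tested.

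H3K27me3 coincided with the list labelled H2A.Z. Shared bp were 2.94-fold (2.69 to 3.22) when shifts stayed within 5 Mb windows. Density shared over longer spans is therefore argued against as the whole cause. Those shifts cannot separate density shared over shorter spans, or the avoidance of active marks and H3K36me3 that both lists had. Of the 7411 merged regions with both lists, 3.99% (Wilson interval 3.57 to 4.46) held a peak of another list. Regions where every list has a peak were thus rare here, but this cannot decide on mapping or copy number artefacts of these lists. Both lists rarely met H3K27ac, H3K4me2 and H3K36me3 over all chromosomes, so a low share was given beforehand. That the list labelled H2A.Z marks chromatin shared with Polycomb domains stays open as a hypothesis, as does cross-reaction of an antibody, and neither was tested.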
